A study of Mus musculus with 28 samples.

How the data were processed

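RNA of 14 kidney samples was measured on 28 arrays, each sample on both designs of an Affymetrix mouse set, 430A and 430B. There were 7 groups of 2 samples: wild type kidneys at E12.5, E13.5 and E16.5 and in the adult, and kidneys of embryos lacking Hoxa11 and Hoxd11 at the same 3 embryonic stages. Per the labels the wild type embryos were CD-1 with the kidneys pooled, and a null sample was the pair of kidneys of an embryo whose strain is not stated. Embryonic RNA (30 ng) was prepared with a column kit and adult RNA (100 ng) with RNAzol, and all RNA went through 2 rounds of in vitro transcription.

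The deposited values are MAS5 signal per probe set on a linear scale, which the authors scaled so that the trimmed mean of each array is the same; it differed by 0.021% between 430A arrays and 0.011% between 430B arrays. MAS5 settings and detection calls were not given. Run records deposited beside the values gave chip type, scanner and scan day, with 7 scan days on 430A and 5 on 430B, and were used only to find batches. For 2 arrays, both of adult replicate 2, the chip type in the run record is that of the other design, and the values were used as labelled.

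Signals below a floor were set to it before taking log2. The floor was the 20th percentile of each design, 86.1 on 430A and 148.1 on 430B. A probe set was tested if its mean log2 value was above the design's median, the 50th percentile, in at least 1 group, which left 14576 probe sets on 430A and 15988 on 430B, 30564 together. Left out were 64 control probe sets per design and the 430B values of 100 probe sets present on both designs. The deposited annotation gave exactly 1 gene symbol to 20380 probe sets on 430A and 14661 on 430B, and only these are named.

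Each design was fitted separately with limma 3.58.1 in R 4.3.3, with a mean per group over all 14 arrays (7 residual degrees of freedom) and eBayes with a mean-variance trend, and contrasts were tested two-sided. P values were adjusted by Benjamini-Hochberg over the probe sets of both designs together, and a call is an adjusted p under 0.05. The 9 contrasts were null against wild type at each stage and averaged over the stages, each wild type stage against adult, and consecutive wild type stages. A moderated F test asked whether the null effect differs between stages. Log2 fold changes are given with their SE, and n is 2 per group. Array quality measures were compared between 6 null and 6 wild type embryonic samples by exact permutation tests.

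Gene lists were written before the data were examined, 21 lists with 354 genes, of which 321 have a probe set. They cover nephron, ureteric, stromal, vascular, blood and neighbouring tissues, growth, stress and metabolism, and sex-linked and Hox genes other than Hoxa11 and Hoxd11. Each list was tested against the other genes with camera at a preset correlation of 0.01 on 430A, with 1 probe set for each of 8886 genes, and adjusted over the lists. Counts of list members come from both designs and are given over all probe sets and adjusted over the list alone.

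The genes named were fixed by a rule before the data were examined. For each contrast these were the 12 largest and 12 smallest log2 fold changes among called probe sets with 1 symbol whose samples did not overlap between the groups. From each list up to 4 called members with the largest change were added, or up to 2 measured members as values where fewer than 2 were called. Hoxa11, Hoxd11 and 10 genes of the F test completed the rule. These 10 had the smallest p after 1 probe set was chosen per gene, so a smaller p of another probe set, as in Zfp266, did not count. A gene with several probe sets was read by the 430A probe set before 430B, then by the one with the highest mean, among those that met the rule. The text prints fewer, in this order.

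Alternatives chosen before the data were examined were quantile normalization, median centring, an offset in place of the floor, a floor at the 40th percentile, no filter, a filter at the 70th percentile, no trend, adjustment within each design, at least 2-fold, replicate number as a block, scan day as a random block, only the 4 samples compared, and leaving out each replicate. For lists they were an estimated correlation and fry. The log2 actin ratio as a covariate, the stage average without E16.5, scan day as a fixed block, and the comparison of probe sets of the same gene were added after seeing the data. The fit and camera were tested on simulated data. A true log2 change of 1 was recovered in 7 of 100 probe sets at null E12.5 and 47 of 99 in the stage average. For wild type E16.5 against adult it was 4 of 100. A true change of 2 was recovered in 57, 92 and 47 of 100. Only 200 probe sets were changed in each simulation, far fewer than were called in the same comparisons of the data. The adjustment was therefore stricter there, and these shares are not the recovery in the data. Genes not called may still have changed. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.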

Results

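Gene expression was measured in whole metanephric kidneys of mouse embryos at E12.5, E13.5 and E16.5 and in whole adult kidneys. Wild type kidneys were sampled at all 3 embryonic stages and in the adult, and kidneys of embryos lacking both Hoxa11 and Hoxd11 (here called null) at the 3 embryonic stages. Each of the 7 groups held 2 samples. Every sample was hybridised to both designs of a mouse array set, 430A and 430B, giving 28 arrays. The deposited MAS5 signals had a trimmed mean of 1500.4 to 1500.7 on every 430A array and 1500.3 to 1500.4 on every 430B array. The number of arrays, 2 per group and design, limits the precision. Values below are log2 fold changes ± SE from limma with n = 2 samples per group, positive where the group named first was higher, and a gene is said to rise or fall only where its adjusted p was under 0.05. Each gene is read by 1 probe set, and where another called probe set of that gene went the other way this is said. Beside each comparison is given how many of the genes named that had other tested probe sets had one called the same way. Unless stated, both samples of a group lay on the same side of both samples of the other for each gene said to rise or fall.

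Embryonic RNA of the 2 genotypes differed in an array measure of amplification, the ratio of 3' to 5' signal of the actin control probe sets. On 430A it was 1.72 ± 0.438 (SD) in the 6 null samples and 3.46 ± 0.495 in the 6 wild type embryonic samples (exact permutation p = 0.00217, two-sided, the smallest p that 6 against 6 samples allow). On 430B it was 1.75 ± 0.425 and 3.50 ± 0.666 (exact permutation p = 0.00217). Over all 6 against 6 samples the Gapdh ratio (exact permutation p = 0.0823 on 430A and 0.0628 on 430B) and the 18S signal (exact permutation p = 0.126 and 0.143) did not pass. At E16.5, however, the 430A Gapdh ratio was 3.305 and 4.253 in the wild type samples and 2.159 and 1.683 in the null samples. There the 18S signal was 30398.6 and 25309.6 against 7097.4 and 2204.5. Median signal was higher in the null samples on 430A (516 ± 30.8 against 431.4 ± 42.1, exact permutation p = 0.00866) and lower on 430B (553.3 ± 122 against 693.7 ± 90.8, exact permutation p = 0.0498). At each stage the null and wild type arrays shared no scan day, so scan day and genotype cannot be told apart within a stage.

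**Figure D1:**
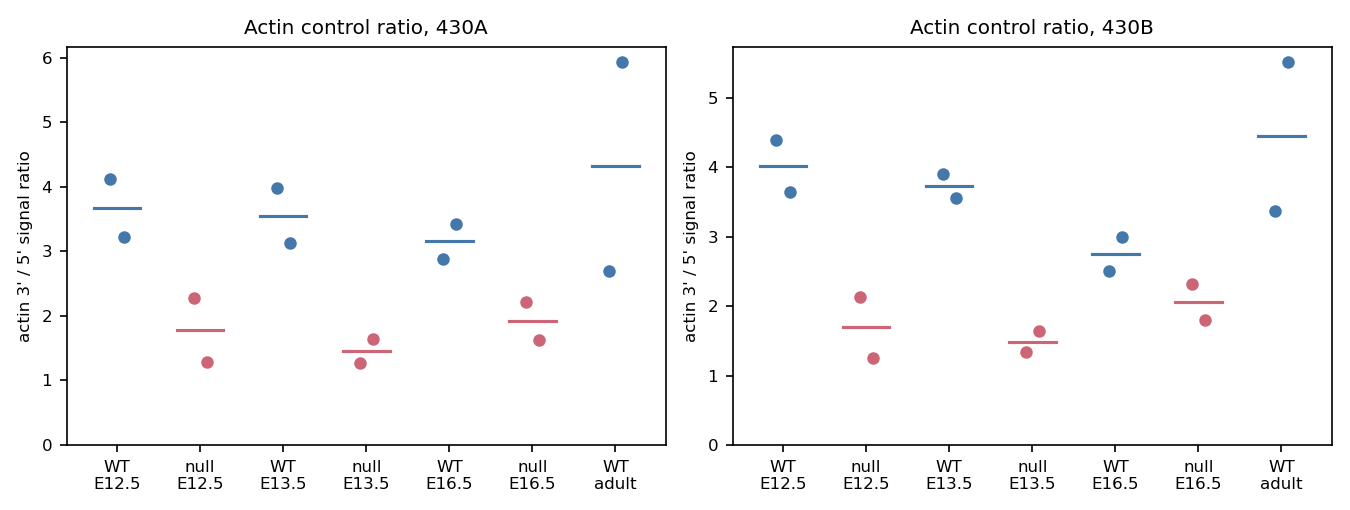
Ratio of 3' to 5' MAS5 signal of the actin control probe sets on each 430A array (left) and 430B array (right), by group; points are arrays, bars the mean of 2, blue wild type and red null. All 6 null samples lie between 1.26 and 2.27 on 430A, below the 6 wild type embryonic samples, which lie between 2.88 and 4.13.

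Hoxa11, a homeobox gene of the metanephric mesenchyme that the null embryos lack, was lower in null kidneys at every stage. Its 430A probe set 1420414 read a mean signal of 2876 ± 784 (SD, n = 2) in wild type and 449.0 ± 72.3 in null kidneys at E12.5. It read 2235 ± 167 and 386.9 ± 49.9 at E13.5, and 1974 ± 48.5 and 213.6 ± 3.75 at E16.5. The fall was -2.66 ± 0.29 at E12.5 (adjusted p = 0.000106), -2.53 ± 0.29 at E13.5 (adjusted p = 0.000181) and -3.21 ± 0.29 at E16.5 (adjusted p = 3.04e-05), which is 6.33-fold, 5.79-fold and 9.24-fold. Hoxd11, its paralogue, which they also lack, is read by the 430A probe set 1450584, which lay under the filter. It gave 406.0 ± 16.2 in wild type and 415.0 ± 162 in null kidneys at E12.5, 382.5 ± 46.5 and 426.8 ± 29.7 at E13.5, and 349.5 ± 32.4 and 332.0 ± 84.1 at E16.5. With no filter its differences were -0.03 ± 0.28, 0.16 ± 0.28 and -0.09 ± 0.28 (adjusted p = 1, 0.788 and 0.941). A probe set outside the altered part of the gene would read no loss, and its place in the gene was not available, so the Hoxd11 value checks nothing.

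**Figure D2:**
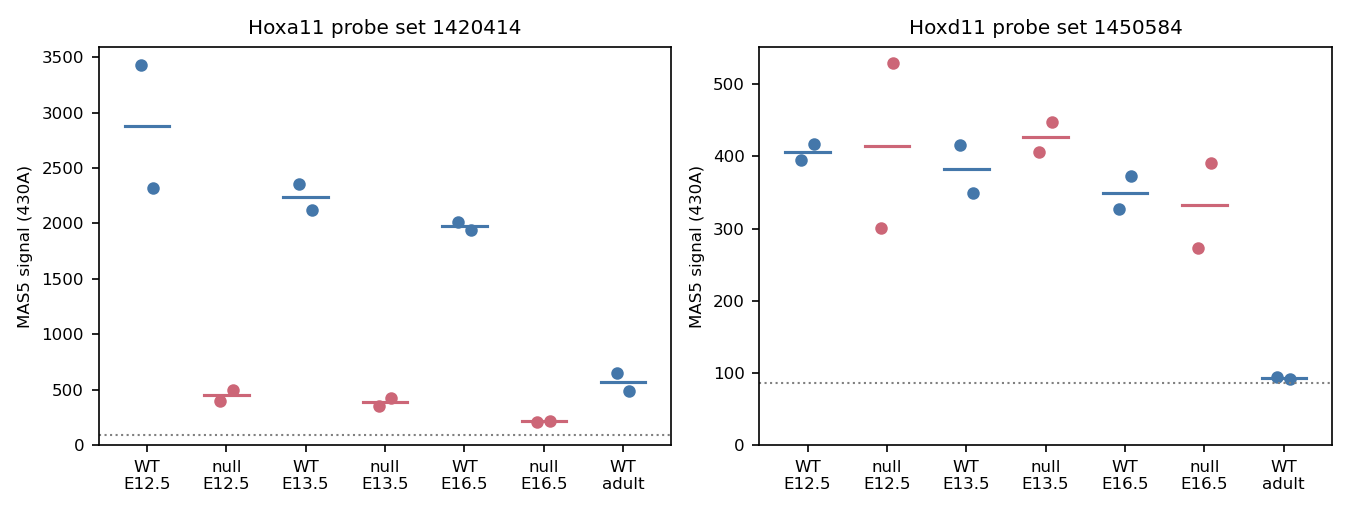
MAS5 signal of the 430A probe sets of Hoxa11 (left) and Hoxd11 (right) in each sample by group, with the mean of 2 as a bar, blue wild type and red null, and the floor of 86.1 dotted. Hoxa11 null samples lie between 211.0 and 500.1 and wild type embryonic samples between 1940 and 3431, while the Hoxd11 samples of both genotypes overlap.

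The comparison at E12.5 asks how the early metanephros differs in embryos lacking Hoxa11 and Hoxd11. Endothelial genes were higher in null kidneys: of 16 measured genes of the endothelium list, 12 rose and 0 fell (12 and 0 adjusted over the list alone). The vascular receptor Tie1 rose most (3.84 ± 0.36, adjusted p = 4.04e-05), followed by the VEGF receptor Flt1 (2.51 ± 0.41), the endothelial cadherin Cdh5 (2.47 ± 0.30) and the VEGF receptor Kdr (2.38 ± 0.30). In wild type E12.5 kidneys the mean log2 of Tie1 (7.33) and Flt1 (7.49) lay near the floor of 6.43, and that of Cdh5 (9.08) and Kdr (10.8) above it. Tie1, which had no other tested probe set, stayed near the floor in wild type E13.5 (6.82) and E16.5 kidneys (7.03). Of 20 renal stroma genes 10 rose and 0 fell (12 and 0 adjusted over the list alone), among them the T-box gene Tbx18 (2.49 ± 0.33), the homeobox gene Meis1 (2.10 ± 0.33) and the matrix gene Tnc (2.07 ± 0.54). Of 16 macrophage and leukocyte genes 7 rose and 0 fell (9 and 0 adjusted over the list alone), such as the complement gene C1qc (2.41 ± 0.55) and the CSF1 receptor gene Csf1r (2.23 ± 0.24).

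The nephron progenitor list at E12.5 split: 2 of 13 genes rose and 4 fell (4 and 4 adjusted over the list alone). Cited1, a marker of uninduced cap mesenchyme, fell (-3.05 ± 0.59, adjusted p = 0.00351), as did Crym (-2.20 ± 0.51), while Osr1 (1.60 ± 0.39) and Sall1 (1.57 ± 0.48), transcription factors of the metanephric mesenchyme, rose. The other probe set of Sall1 gave -0.56, not called. In the ureteric trunk list 1 of 19 genes rose, the transcription factor Gata3 (2.46 ± 0.53), and 6 fell (2 and 6 adjusted over the list alone), led by the calcium-binding protein gene Calb1 (-2.28 ± 0.30, adjusted p = 0.000368). Early nephron genes rose in 6 of 16 and fell in 2 (7 and 2 adjusted over the list alone), with Greb1 (2.40 ± 0.47) and the LIM homeobox gene Lhx1 (2.38 ± 0.61) the largest; another called probe set of Greb1 fell. Podocyte genes rose in 5 of 15 and fell in 0 (6 and 0 adjusted over the list alone), as in Synpo (1.80 ± 0.48) and the actin-bundling protein gene Actn4 (1.74 ± 0.23). In the ureteric tip list 2 of 13 rose, Sox9 (2.22 ± 0.43) and the chemokine receptor gene Cxcr4 (1.63 ± 0.51), and 0 fell (2 and 0 adjusted over the list alone). Of 22 other Hox genes 7 rose and 0 fell (7 and 0 adjusted over the list alone), with Hoxa5 (2.49 ± 0.39) and Hoxa3 (1.79 ± 0.31) the largest, while another probe set of Hoxa5 fell (-1.18). With median centring 4 other Hox genes rose and 4 fell. Markers of other tissues rose too. In the muscle and cartilage list 2 of 5 genes rose, the collagen genes Col9a1 (2.03 ± 0.37) and Col2a1 (1.87 ± 0.39), and 0 fell (2 and 0 adjusted over the list alone). Of 8 neuron genes 2 rose, Elavl4 (2.05 ± 0.32) and Nefm (1.37 ± 0.37), and 0 fell (2 and 0 adjusted over the list alone). Of 8 adrenal and gonad genes 1 rose, Dbh (1.40 ± 0.36), and 0 fell (1 and 0 adjusted over the list alone). As lists these 3 did not pass camera (adjusted p = 0.364, 0.114 and 0.5). Their folds with the actin covariate were 1.36 (Col9a1), 1.82 (Col2a1), 2.08 (Elavl4), 1.30 (Nefm) and 1.05 (Dbh), with Elavl4 alone still called.

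Across all genes at E12.5 the largest rises were in the DNA demethylase gene Tet1 (5.59 ± 0.41), Zfp704 (5.51 ± 0.55), Dpysl3 (5.24 ± 0.38), the histone demethylase gene Kdm6b (5.23 ± 0.78) and Vwf, the von Willebrand factor of endothelium (5.20 ± 0.43). Falls were largest in AI506816 (-5.02 ± 1.5), the retinaldehyde dehydrogenase gene Aldh1a1 (-3.77 ± 0.34), Adamts16 (-3.56 ± 0.78), Spink2 (-3.48 ± 0.78) and Cpa1 (-3.47 ± 0.36). Tet1 and Zfp704 lay at the floor in both wild type samples, and Aldh1a1, Spink2 and Cpa1 in both null samples, so that their folds are lower bounds. The other probe set of Tet1 gave -0.55 and that of Zfp704 0.59, neither called. Of 18 genes named at E12.5 with other tested probe sets, 9 had one called the same way. The camera test passed the endothelium list (adjusted p = 1.54e-05; adjusted p = 0.28 with an estimated correlation), renal stroma (4.31e-05; 0.169 with an estimated correlation) and macrophages (0.00171; 0.534 with an estimated correlation), all up. Less the median of all genes on 430A, which was 0.11, their medians were 1.42, 1.01 and 1.14. The cell proliferation list was lower (median -0.49 less all genes, adjusted p = 0.0165, and 0.169 with an estimated correlation), but with quantile normalization its median was 0.04 above all genes (adjusted p = 0.609; 0.0101 to 0.609 over the settings chosen beforehand). Of its 20 genes 0 rose and 3 fell (0 and 3 adjusted over the list alone), the survivin gene Birc5 (-1.49 ± 0.38) and the ribonucleotide reductase gene Rrm2 (-0.93 ± 0.24) first. The other 17 lists did not pass (adjusted p 0.0724 to 0.935).

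At E12.5 limma called 5685 of 30564 probe sets, 3793 up and 1892 down. Of 769 genes with several called probe sets, 69 (9.0%) had called probe sets in both directions. Median centring turned the balance to 2841 up and 3507 down. Leaving out wild type replicate 1 or 2 gave 2049 or 2220 calls, and leaving out null replicate 1 or 2 gave 3540 or 2410. With the actin ratio as a covariate 779 probe sets were called. With that covariate the endothelium (adjusted p = 0.000343), stroma (0.00198) and proliferation (0.032) lists passed and the macrophage list did not (0.0857). Tie1 (4.01), Flt1 (2.77), Cdh5 (2.35), Calb1 (-2.33) and Cited1 (-4.03) stayed called. Apart from the markers of other tissues given, the genes named at E12.5 that lost their call with it were Kdm6b (2.92), AI506816 (-6.96), Adamts16 (-5.02), Spink2 (-1.22), Tnc (1.84) and C1qc (1.87). The same held for Birc5 (-1.76), Rrm2 (-0.62), Crym (-1.67), Osr1 (1.23), Sall1 (1.44), Gata3 (1.76) and Greb1 (1.24), and for Lhx1 (1.46), Synpo (1.93), Sox9 (1.87), Cxcr4 (2.44), Hoxa5 (2.01) and Hoxa3 (1.51).

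At E13.5, a day later, the same question was asked of 30564 probe sets. Endothelial genes again rose, 11 of 16 with 0 falling (11 and 0 adjusted over the list alone), led by Tie1 (3.45 ± 0.36, adjusted p = 8.42e-05), Flt1 (2.89 ± 0.41) and Kdr (2.70 ± 0.30). Renal stroma genes rose in 10 of 20 and fell in 0 (10 and 0 adjusted over the list alone). They included Dlk1, a Notch-like ligand gene (2.49 ± 0.48), Tbx18 (2.39 ± 0.33) and the collagen I gene Col1a2 (2.23 ± 0.24, adjusted p = 0.000112). In the nephron progenitor list 4 of 13 rose and 3 fell (6 and 3 adjusted over the list alone). Cited1 fell (-3.52 ± 0.59, adjusted p = 0.00137) and Crym fell (-2.03 ± 0.51). On the probe set read, Sall1 rose by at least 3.13 ± 0.48, its wild type samples being at the floor, and the integrin gene Itga8 rose (2.47 ± 0.42). The other probe set of Sall1 gave 0.48 and that of Itga8 -0.3, neither called. Early nephron genes rose in 8 of 16 and fell in 0 (9 and 0 adjusted over the list alone), with Lhx1 (4.06 ± 0.61) and Greb1 (3.90 ± 0.47, adjusted p = 0.000237) first.

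Podocyte genes at E13.5 rose in 7 of 15 and fell in 0 (7 and 0 adjusted over the list alone), the transcription factor Foxc2 (1.83 ± 0.26) and the phospholipase gene Plce1 (1.82 ± 0.32) among them. Other Hox genes rose in 9 of 22 and fell in 0 (9 and 0 adjusted over the list alone), with Hoxa5 (2.89 ± 0.39) and Hoxb3 (2.61 ± 0.56) the largest, while another probe set of Hoxa5 fell (-1.71). Gata3 rose (2.99 ± 0.53) and Calb1 fell (-1.36 ± 0.30), each the only called member in its direction among 19 ureteric trunk genes (1 and 1 adjusted over the list alone), though another probe set of Calb1 rose (1.67). In the ureteric tip list Sox9 (2.09 ± 0.43) and the Ret pathway inhibitor Spry1 (1.03 ± 0.29) rose, 2 of 13, and 0 fell (2 and 0 adjusted over the list alone). Of 16 macrophage genes 2 rose, C1qa (1.44 ± 0.49) and Csf1r (1.37 ± 0.24), and 0 fell (1 and 0 adjusted over the list alone). Of 6 erythroid genes 0 rose and 1 fell (0 and 1 adjusted over the list alone), the embryonic globin gene Hbb-y (-1.17 ± 0.32), and the value of Hba-x was -0.78 ± 0.40. Neuron genes rose in 2 of 8, Nefm (1.62 ± 0.37) and Elavl4 (1.17 ± 0.32), and fell in 0 (3 and 0 adjusted over the list alone). In the muscle and cartilage list Col2a1 rose (2.03 ± 0.39) and Acta1 fell (-1.91 ± 0.55), each alone in its direction among 5 genes (1 and 1 adjusted over the list alone). In the adrenal and gonad list Inha rose (1.02 ± 0.29), 1 of 8, and 0 fell (1 and 0 adjusted over the list alone). The folds of Nefm, Elavl4, Col2a1, Acta1 and Inha with the actin covariate were 1.53, 1.2, 1.97, -2.83 and 0.69, none called. In the proliferation list 2 of 20 genes rose, Plk1 (0.86 ± 0.27) and Mcm5 (0.73 ± 0.25), and 1 fell, Birc5 (-1.22 ± 0.38), with 0 and 0 adjusted over the list alone. With median centring 0 of these genes rose and 6 fell.

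The largest rises of all genes at E13.5 were in Kdm6b (6.10 ± 0.78), the kinase gene Dyrk2 (5.57 ± 0.47), the transcription factor Nfib (5.40 ± 0.41) and Zfp266, by at least 5.38 ± 0.45. Falls were largest in 4933438K21Rik (-5.18 ± 0.44 or lower), D5Ertd615e (-4.40 ± 0.58) and Nat8f3 (-3.84 ± 0.52 or lower). The other probe sets of Kdm6b gave -0.70 to 1.16, those of Dyrk2 -0.67 to 0.42, those of Zfp266 -0.83 to 0.78 and that of Nat8f3 -0.05, none called. Of 19 genes named at E13.5 with other tested probe sets, 6 had one called the same way. The camera test passed 5 lists, all up. These were endothelium (median 1.16 less all genes, whose median was 0.13; adjusted p = 0.000394), stroma (0.94; 0.00217), other Hox genes (0.56; 0.0151), early nephron (0.96; 0.0286) and podocytes (0.78; 0.0286). With an estimated correlation their adjusted p was 0.348 to 0.58. The other 16 lists gave adjusted p 0.0671 to 0.959. In all, 7152 probe sets were called, and called probe sets went both ways in 93 of 982 genes that had several (9.5%). They were 4410 up and 2742 down, against 3689 up and 3070 down with median centring.

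The E13.5 count fell to 357 when only the 4 samples compared were fitted. It was 3580 without wild type replicate 2, 4210 without null replicate 1 and 4661 without null replicate 2. With the actin covariate it was 1208, and of the 5 lists the endothelium list alone passed (adjusted p = 0.0139; stroma 0.0792, early nephron 0.639, podocytes 0.315, other Hox genes 0.24). Tie1 (3.64), Flt1 (3.20), Col1a2 (2.30), Cited1 (-4.67) and Greb1 (2.53) stayed called with it. Besides the markers of other tissues given, calls were lost for Kdm6b (3.72), Nat8f3 (-3.66), Dlk1 (1.56), Lhx1 (2.98), Plce1 (1.64), Hoxb3 (1.80), Itga8 (2.17), Crym (-1.41) and Gata3 (2.17). Also lost were those of Calb1 (-1.42), Sox9 (1.68), Spry1 (0.54), Hbb-y (-1.50), C1qa (0.83), Csf1r (1.28), Birc5 (-1.54), Plk1 (0.42) and Mcm5 (0.79).

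At E16.5, when nephrons of all segments are forming, the endothelium list again stood out. Of its 16 genes 10 rose and 1 fell in null kidneys (13 and 1 adjusted over the list alone). Here Tie1 (4.46 ± 0.36, adjusted p = 1.27e-05), the adhesion receptor Pecam1 (2.13 ± 0.34), endoglin, Eng (2.10 ± 0.33) and Kdr (2.00 ± 0.30) rose. Erythroid genes fell in 4 of 6 and rose in 0 (0 and 4 adjusted over the list alone). They were the embryonic globin genes Hbb-y (-3.07 ± 0.32, adjusted p = 6.16e-05) and Hba-x (-1.57 ± 0.40), the red cell anion exchanger Slc4a1 (-1.60 ± 0.42) and Add2 (-1.25 ± 0.31), of which another probe set rose (1.36). In the nephron progenitor list 1 of 13 rose, Sall1 (1.61 ± 0.48, while its other probe set fell, -1.72), and 3 fell (1 and 3 adjusted over the list alone). These were Eya1 (-2.11 ± 0.43), Gdnf, the ligand of Ret that drives ureteric branching (-1.10 ± 0.25, adjusted p = 0.00459), and Six2, which maintains progenitors (-0.95 ± 0.30, adjusted p = 0.0254). Among 13 ureteric tip genes Spry2 (-2.06 ± 0.28) and Myb (-1.19 ± 0.43) fell, 2 in all, and 0 rose (0 and 1 adjusted over the list alone).

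Calb1 (-2.95 ± 0.30) and the water channel gene Aqp3 (-1.90 ± 0.32) fell at E16.5, while the keratin gene Krt19 rose (1.73 ± 0.31). Another probe set of Aqp3 rose (2.72). Of 19 ureteric trunk genes 2 rose and 2 fell (2 and 2 adjusted over the list alone). Podocyte genes rose in 6 of 15 and fell in 0 (6 and 0 adjusted over the list alone), with the slit diaphragm gene Nphs1 (2.17 ± 0.36), Ptpro (2.05 ± 0.29) and Podxl (2.01 ± 0.31) the largest, although another probe set of Podxl fell (-1.52). Proximal tubule genes rose in 6 of 24 and fell in 2 (6 and 2 adjusted over the list alone). Slc5a12 (-2.46 ± 0.53) and Kap (-1.81 ± 0.26) fell and the organic anion transporter Slc22a8 rose (1.68 ± 0.40). In the loop of Henle and distal tubule list 2 of 13 rose, uromodulin, Umod (1.28 ± 0.30), and Egf (1.26 ± 0.28), and 2 fell (2 and 2 adjusted over the list alone), Slc8a1 (-2.11 ± 0.39) and Pvalb (-1.85 ± 0.33 or lower). Stroma genes rose in 7 of 20 and fell in 1 (7 and 1 adjusted over the list alone), Dlk1 (2.74 ± 0.48) and decorin, Dcn (1.80 ± 0.54) first. Of 11 fatty acid oxidation genes 5 rose and 0 fell (5 and 0 adjusted over the list alone), with the carnitine palmitoyltransferase genes Cpt2 (1.45 ± 0.31) and Cpt1a (1.32 ± 0.27) first, although both other probe sets of Cpt1a fell (-1.66 and -1.58). Of 22 other Hox genes 2 rose, Hoxc10 (1.99 ± 0.33) and Hoxc5 (1.89 ± 0.40), and 6 fell (2 and 7 adjusted over the list alone), Hoxd13 (-1.61 ± 0.57) first. Early nephron genes rose in 2 of 16, Pax8 (1.43 ± 0.27) first, and fell in 2 (2 and 2 adjusted over the list alone), the Notch modifier Lfng (-1.46 ± 0.30) first. Of 8 neuron genes 2 fell, Elavl4 (-1.24 ± 0.32) and Th (-1.06 ± 0.36), and 1 rose, Nefm (1.09 ± 0.37), with 1 and 2 up and down adjusted over the list alone. Col2a1 rose (1.33 ± 0.39), 1 of 5 muscle and cartilage genes, and 0 fell (1 and 0 adjusted over the list alone). Of 8 adrenal and gonad genes 1 rose, Nr5a1 (at least 1.24 ± 0.40), and 1 fell, Star (-1.08 ± 0.28), with 1 and 1 adjusted over the list alone. Elavl4 (-1.23) and Star (-1.19) stayed called with the actin covariate, and Th (-1.02), Nefm (1.05), Col2a1 (1.29) and Nr5a1 (0.98) did not. In the proliferation list 3 of 20 genes rose, Mcm5 (1.35 ± 0.25), Mcm6 (1.27 ± 0.26) and Mcm7 (0.58 ± 0.19), and 0 fell (2 and 0 adjusted over the list alone). Another probe set of Mcm6 fell (-1.38).

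Among all genes at E16.5 the largest rises were in Mfap4, a microfibril gene (6.06 ± 0.38), Ager (5.10 ± 0.62), Rtl3 (5.05 ± 0.61), Abtb2 (4.84 ± 0.62) and the deacetylase gene Sirt2 (4.74 ± 0.26). All but Rtl3 were at the floor in both wild type samples, so that their folds are lower bounds. The largest falls were in Xist, the RNA of the inactive X chromosome (-5.94 ± 1.08, adjusted p = 0.00123), Mapk1ip1l (-4.74 ± 0.56), the splicing factor gene Rbm39 (-4.58 ± 0.56) and Ap1s3 (-4.53 ± 0.43). The other probe set of Abtb2 gave -0.96, that of Mapk1ip1l -0.57 and that of Xist -2.14, none called. Of 28 genes named at E16.5 with other tested probe sets, 11 had one called the same way. Embryo sex is not in the labels, and the fall in Xist may not be read as an effect of genotype. The camera test passed endothelium up (median 1.05 less all genes, whose median was 0.13; adjusted p = 0.00181) and erythroid cells down (-1.55; adjusted p = 0.0244). Each had an adjusted p = 0.732 with an estimated correlation. The other 19 lists gave adjusted p 0.282 to 0.919.

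Of the tested probe sets 10728 were called at E16.5, 4856 up and 5872 down, and of 1620 genes with several called probe sets 363 (22.4%) had them in both directions. The balance turned with scaling: 4712 up and 4274 down with quantile normalization, and 6407 up and 4007 down with median centring. The null E16.5 arrays were read on another scanner than all other arrays, and the Gapdh ratio and 18S signal given for E16.5 were not adjusted for. Without wild type replicate 1 or 2 there were 6098 or 6684 calls, and without null replicate 2 there were 6701. With the actin covariate the endothelium list passed (adjusted p = 0.00503) and the erythroid list did not (0.078), with Tie1 at 4.57, Hbb-y at -3.25, Gdnf at -1.02 and Six2 at -1.12, all called. Sall1 (1.52), Myb (-1.28), Hoxd13 (-1.60) and Mcm7 (0.60) lost their call with it.

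Averaged over the 3 stages with equal weight, Tie1 was higher by 3.92 ± 0.21, adjusted p = 2.85e-07, Kdr by 2.36 ± 0.17, Flt1 by 1.93 ± 0.24 and Robo4 by 1.73 ± 0.16. In all, 13 of 16 endothelial genes rose and 0 fell (14 and 0 adjusted over the list alone). Stroma genes rose in 15 of 20 and fell in 0 (16 and 0 adjusted over the list alone), with Dlk1 (2.37 ± 0.27), Col1a2 (1.90 ± 0.14, adjusted p = 1.24e-06), Tnc (1.60 ± 0.31) and Tbx18 (1.54 ± 0.19) first. With median centring 14 rose and 1 fell. Calb1 fell (-2.20 ± 0.18, adjusted p = 2.2e-06), as did Cited1 (-2.16 ± 0.34, adjusted p = 0.000222), Eya1 (-1.68 ± 0.25) and Crym (-1.43 ± 0.29), while Sall1 (2.10 ± 0.28), Gata3 (2.03 ± 0.31), Lhx1 (2.56 ± 0.35) and Greb1 (2.45 ± 0.27) rose. Podocyte genes rose in 9 of 15 and fell in 0 (9 and 0 adjusted over the list alone), with Actn4 (1.60 ± 0.14) and Podxl (1.39 ± 0.18) first. Macrophage genes rose in 6 of 16 and fell in 0 (6 and 0 adjusted over the list alone), with C1qa (1.83 ± 0.28), C1qc (1.79 ± 0.32) and Csf1r (1.72 ± 0.14) first. Erythroid Hbb-y (-1.54 ± 0.19) and Hba-x (-0.89 ± 0.23) fell, and Hoxa5 (1.87 ± 0.23), Hoxc10 (1.83 ± 0.19) and the cartilage collagen gene Col2a1 (1.74 ± 0.22) and Nefm (1.36 ± 0.21) rose. Of 20 proliferation genes 4 fell, Birc5 (-0.92 ± 0.22) first, and 2 rose, the helicase subunit gene Mcm5 (0.70 ± 0.14) first, with 2 and 4 up and down adjusted over the list alone. Median centring gave 9 falls and 1 rise.

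**Figure D3:**
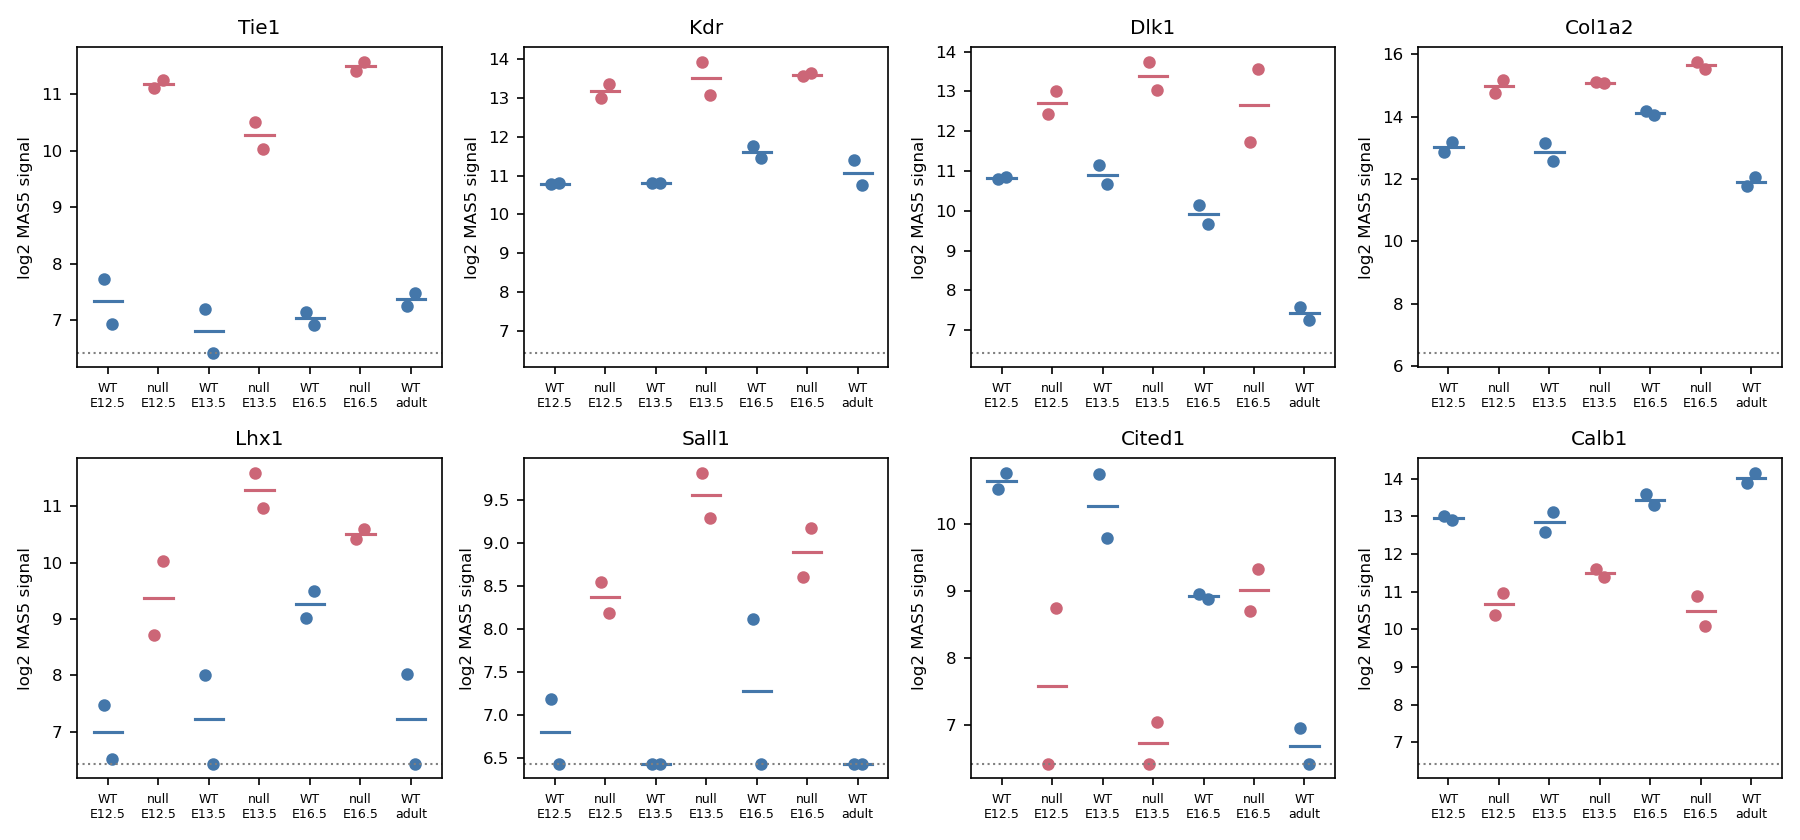
Log2 MAS5 signal of 8 genes in each sample by group, with the mean of 2 as a bar, blue wild type and red null, and the floor dotted. Tie1, Kdr, Dlk1, Col1a2, Lhx1 and Sall1 lie higher and Calb1 lower in both null samples than in both wild type samples of each stage, and Cited1 lies lower at E12.5 and E13.5. Each gene is shown by 1 probe set. Another probe set of Sall1 fell at E16.5 (-1.72), and another of Calb1 rose at E13.5 (1.67).

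The largest rises in the stage average were in Zfp704 (3.97 ± 0.32), the basement membrane gene Nid1 (3.92 ± 0.24), the axon guidance ligand gene Slit3 (3.92 ± 0.30) and Tie1. The largest falls were in Ap1s3 (-3.23 ± 0.25), Hoxa11 (-2.80 ± 0.17, adjusted p = 5.7e-07), the La protein gene Ssb (-2.70 ± 0.33), Gigyf2 (-2.69 ± 0.48) and the adult beta globin gene Hbb-b2 (-2.68 ± 0.42). The other probe set of Zfp704 gave 0.46, that of Nid1 0.64 and that of Hbb-b2 -0.61, none called, and of 19 genes named in the average with other tested probe sets 8 had one called the same way. The camera test passed endothelium (median 1.18 less all genes, whose median was 0.13; adjusted p = 5.78e-05) and stroma (0.79; adjusted p = 0.00108), each with adjusted p = 0.463 with an estimated correlation. The other 19 lists gave adjusted p 0.0791 to 0.944. Of the tested probe sets 14320 were called, 7148 up and 7172 down, and 6795 of these changed at least 2-fold. Called probe sets went both ways in 545 of 2445 genes that had several (22.3%), among them Sall1, Greb1 and Hoxa5, whose other probe sets included falls of -0.60, -0.71 and -1.43. In the wild type comparisons that share was 3.7%, 3.9% and 8.8% for E12.5, E13.5 and E16.5 against adult and 12.2% for E16.5 against E13.5. With the actin covariate 3395 were called, and endothelium (adjusted p = 0.00057) and stroma (0.0265) passed. The mean of a list less all genes went from 1.214 to 1.069 with it for endothelium and from 0.853 to 0.685 for stroma. It went from 0.607 to 0.465 for podocytes, 0.589 to 0.150 for early nephron, 0.538 to 0.171 for macrophages, 0.255 to 0.055 for other Hox genes and -0.813 to -0.545 for erythroid cells. Calls were lost for Eya1 (-0.80), Crym (-0.93), Gata3 (1.37), Lhx1 (1.69), Tnc (1.38), C1qa (1.34), C1qc (1.28), Hba-x (-0.59), Nefm (1.29), Birc5 (-1.17), Mcm5 (0.75), Gigyf2 (-0.49) and Hbb-b2 (-1.83), while the median SE of the called probe sets rose from 0.213 to 0.419. Cited1, Crym, Tbx18, Hba-x, Birc5, Mcm5 and Hoxa5 did not separate the genotypes in every stage. Both wild type samples lay at the floor for Nid1 and Zfp704 at E12.5 and E13.5, Slit3 at E16.5 and Sall1 at E13.5, so that these average folds are lower bounds.

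Whether the null effect differs between stages was tested with a moderated F test, which called 4364 probe sets. The 3 comparisons share no array but use the same estimate of spread for each probe set. Across the 430A probe sets their log2 fold changes correlated at 0.822 between E12.5 and E13.5, at 0.491 between E13.5 and E16.5 and at 0.367 between E12.5 and E16.5; probe sets are not independent replicates. In all 3 stages 1108 probe sets were called up, where 87.0 would be called with independent lists, and 522 down, where 32.6 would. With a shared estimate of spread the lists are not independent, so some excess arises without a common effect of genotype. By contrast 815 were called up in 1 stage and down in another. Gsdme, a pore-forming gasdermin gene (adjusted p = 2.62e-05), had effects of 1.14, 1.02 and -3.53 at E12.5, E13.5 and E16.5. Zfhx3 (adjusted p = 3e-05) went from 3.68 and 4.24 to -2.39. The nuclear receptor corepressor gene Nrip1 (3e-05) went from 4.47 and 3.58 to -0.76, and the ephrin receptor gene Epha7 (3.78e-05) from 4.05 and 3.96 to -2.40. Sirt2 (3.08e-05) went from 0.36 and 0.32 to 4.74, Mfap4 (7.89e-05) from 0.59 and 0.04 to 6.06, and Wdr26 (7.37e-05) from 3.32 and 3.22 to -1.47. Sirt2 and Mfap4 were at the floor in wild type kidneys at E16.5 and Epha7 in wild type kidneys at E12.5 and E13.5, so that these effects are lower bounds. The wild type mean log2 of Gsdme was 8.54, 8.98 and 12.68 over the stages, and the null mean 9.68, 10 and 9.15. In Sirt2 it was 10.63, 10.08 and 6.43 in wild type and 11, 10.4 and 11.17 in null kidneys. The null means of Zfhx3 (11.84, 11.56 and 8.71) and Epha7 (10.48, 10.39 and 7.72) moved as well. The wild type E16.5 samples had the highest 430A Gapdh ratios and 18S signals of the embryos. The count was 1732 and 2179 without wild type E16.5 replicate 1 and 2, and 1900 and 2868 without null E16.5 replicate 1 and 2. It was 2904 and 2903 without wild type E12.5 replicate 1 and 2, and 2438 with the actin covariate.

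**Figure D4:**
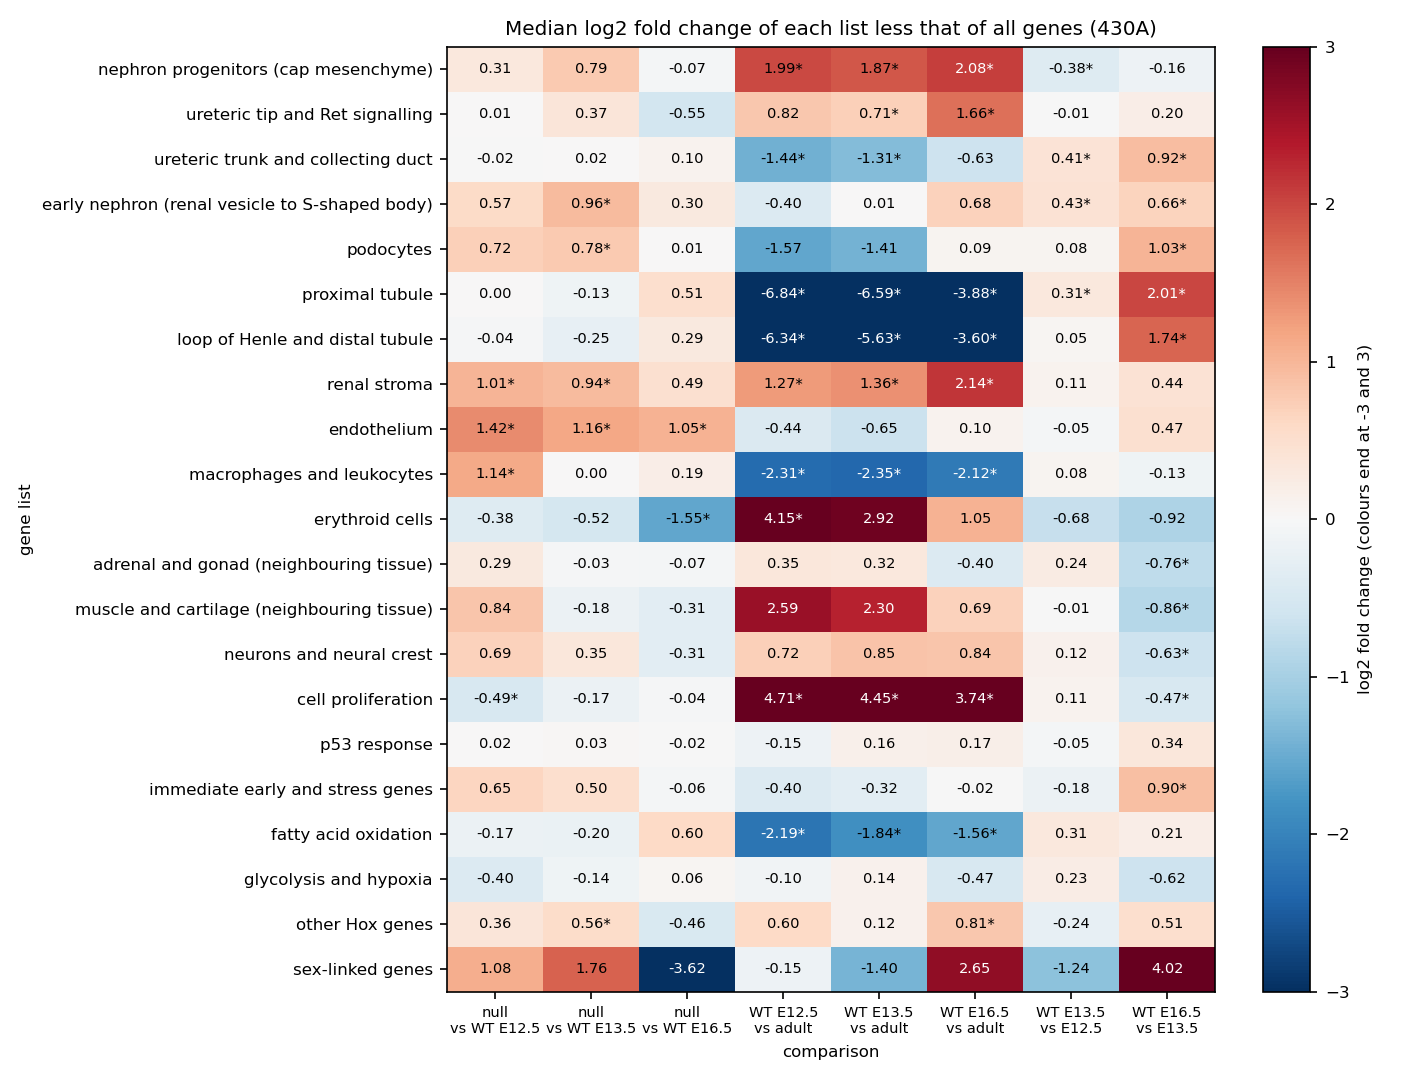
Median log2 fold change of each of the 21 gene lists on 430A, less the median of all genes, for 8 comparisons; red is higher and blue lower in the group named first, and an asterisk marks an adjusted camera p under 0.05. Endothelium is higher in null kidneys at all 3 stages (1.42, 1.16 and 1.05), and proximal tubule is lower in wild type embryos than in adults (-6.84, -6.59 and -3.88).

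Wild type kidneys of each embryonic stage were set against adult kidneys, the reference named in the series, to ask what the developing kidney expresses that the adult does not and the reverse. At E12.5 the functional nephron genes were low: 23 of 24 proximal tubule genes fell and 0 rose (0 and 23 adjusted over the list alone), with Miox (-9.14 ± 0.41, adjusted p = 3.52e-09), the fatty acid transporter Slc27a2 (-8.46 ± 0.41) and Cyp2j5 (-7.90 ± 0.50) first. All 13 measured genes of the loop of Henle and distal tubule fell (0 and 13 adjusted over the list alone), led by Umod (-8.13 ± 0.30, adjusted p = 1.44e-09), the thiazide-sensitive cotransporter Slc12a3 (-7.13 ± 0.35) and Egf (-6.94 ± 0.28). Of 20 proliferation genes 19 rose and 0 fell (20 and 0 adjusted over the list alone), as in the cell cycle kinase gene Cdk1 (6.11 ± 0.35, adjusted p = 1.99e-08) and Mki67 (5.17 ± 0.30). Nephron progenitor genes rose in 11 of 13 and fell in 0 (12 and 0 adjusted over the list alone), Gdnf (5.25 ± 0.25, adjusted p = 4.82e-09) and Eya1 (5.10 ± 0.43) first. Stroma genes rose in 13 of 20 and fell in 1 (13 and 1 adjusted over the list alone), with the stromal progenitor factor Foxd1 (5.43 ± 0.33) and Fat4 (4.07 ± 0.41) first.

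Ureteric trunk genes at E12.5 fell in 11 of 19 and rose in 1 (1 and 11 adjusted over the list alone), with the water channel genes Aqp2 (-5.01 ± 0.36) and Aqp3 (-4.89 ± 0.32) first. All 11 fatty acid oxidation genes fell (0 and 11 adjusted over the list alone), Ehhadh (-7.06 ± 0.36) and the nuclear receptor gene Ppara (-5.30 ± 0.72) first. Also 11 of 16 macrophage genes fell and 0 rose (0 and 12 adjusted over the list alone), Cd52 (-4.65 ± 0.55) and Cd14 (-3.64 ± 0.44) first. The embryonic globin genes Hbb-y (8.48 ± 0.32, adjusted p = 1.59e-09), Hba-x (7.91 ± 0.40) and Hbb-bh1 (7.72 ± 0.62) rose and were the largest rises of all genes; of 6 erythroid genes 3 rose and 0 fell (3 and 0 adjusted over the list alone). Next came 6330403K07Rik (7.08 ± 0.20) and the retinoic acid binding protein gene Crabp1 (6.81 ± 0.37). Miox fell most, followed by Nceh1 (-9.11 ± 0.44) and the kallikrein gene Klk1 (-8.73 ± 0.30). Of 13 ureteric tip genes 5 rose and 0 fell (5 and 0 adjusted over the list alone), with Etv4 (4.33 ± 0.67) and Wnt11 (2.90 ± 0.34), targets of Ret signalling, first. The early nephron list split with 3 up and 5 down (3 and 5 adjusted over the list alone): Wnt4, which drives nephron induction, rose (4.50 ± 0.45) and Papss2 fell (-5.39 ± 0.33). So did the podocyte list, with 4 up and 9 down (4 and 9 adjusted over the list alone), Foxc2 rising (3.41 ± 0.26) and the glomerular collagen gene Col4a4 falling (-7.81 ± 0.54).

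The camera test at E12.5 against adult passed 9 of 21 lists, 4 up and 5 down. These were proximal tubule (median -6.84 less all genes, whose median was 0.16; adjusted p = 7.95e-18), proliferation (4.71; 2.27e-12), loop and distal tubule (-6.34; 4.71e-10). They further included fatty acid oxidation (-2.19; 6.23e-05), macrophages (-2.31; 8.9e-05), nephron progenitors (1.99; 0.000172), ureteric trunk (-1.44; 0.000172), stroma (1.27; 0.00427) and erythroid cells (4.15; 0.0186). With an estimated correlation proliferation (adjusted p = 0.00218) and loop and distal tubule (0.0113) passed, and the others gave adjusted p 0.0774 (proximal tubule and progenitors) to 0.235. Of the tested probe sets 10794 were called, 6167 up and 4627 down. Of 15 genes named here with other tested probe sets, 13 had one called the same way. RNA extraction and RNA input (30 ng for embryos, 100 ng for adults) also differ between embryonic and adult samples in the labels. The 430A 18S signal was 3220.4 and 5554.0 at E12.5 and 3946.3 and 3328.0 at E13.5, against 41058.2 and 32587.7 in the adult samples. Hbb-y, Hbb-bh1, 6330403K07Rik, Crabp1, Gdnf and Etv4 were at the floor in both adult samples and Miox, Nceh1, Klk1, Cyp2j5, Slc12a3, Cd52 and Col4a4 in both E12.5 samples, so that these folds are lower bounds.

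The E13.5 kidneys were set against the same 2 adult samples. Hbb-y rose most, by at least 9.34 ± 0.32, adjusted p = 6.89e-10, then 6330403K07Rik, by at least 7.06 ± 0.20, Hba-x (6.99 ± 0.40) and the imprinted gene Mest (6.64 ± 0.20). The largest falls were in Nceh1 (-9.11 ± 0.44 or lower), Klk1 (-8.73 ± 0.30 or lower), and Rdh16f2 (-8.40 ± 0.42 or lower). Of 24 proximal tubule genes 23 fell and 0 rose (0 and 23 adjusted over the list alone), Miox (-8.05 ± 0.41) and Slc27a2 (-7.99 ± 0.41) first. All 13 loop and distal tubule genes fell (0 and 13 adjusted over the list alone), Umod (-7.62 ± 0.30) and Slc12a3 (-7.13 ± 0.35 or lower) first. All 20 proliferation genes rose (20 and 0 adjusted over the list alone; with median centring 19 rose), as in Cdk1 (6.45 ± 0.35, adjusted p = 1.45e-08) and Mki67 (5.25 ± 0.30). Nephron progenitor genes rose in 9 of 13 and fell in 0 (9 and 0 adjusted over the list alone), Gdnf (at least 4.76 ± 0.25) and Eya1 (4.34 ± 0.43) first. Stroma genes rose in 15 of 20 and fell in 1 (16 and 1 adjusted over the list alone), Foxd1 (4.79 ± 0.33) and Meis1 (at least 3.81 ± 0.33) first. Ureteric tip genes rose in 6 of 13 and fell in 0 (6 and 0 adjusted over the list alone), Etv4 (at least 3.89 ± 0.67) and Wnt11 (2.87 ± 0.34) first.

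Ureteric trunk genes at E13.5 fell in 10 of 19 and rose in 1 (2 and 10 adjusted over the list alone), Aqp2 (-4.59 ± 0.36) and Aqp3 (-4.22 ± 0.32) first. Fatty acid oxidation genes fell in 9 of 11 and rose in 0 (0 and 10 adjusted over the list alone), Ehhadh (-7.32 ± 0.36) and Ppara (-4.56 ± 0.72) first. Macrophage genes fell in 10 of 16 and rose in 0 (0 and 12 adjusted over the list alone), Cd14 (-4.33 ± 0.44) and Cd52 (-4.14 ± 0.55) first. The camera test passed proximal tubule (median -6.59 less all genes, whose median was 0.14; adjusted p = 2.3e-17), proliferation (4.45; 9.1e-13), loop and distal tubule (-5.63; 5.81e-10), fatty acid oxidation (-1.84; 0.000251). It also passed macrophages (-2.35; 0.00026), stroma (1.36; 0.000358), nephron progenitors (1.87; 0.00192), ureteric trunk (-1.31; 0.00196) and ureteric tip (0.71; 0.0313). With an estimated correlation proliferation (adjusted p = 0.00196) and loop and distal tubule (0.0116) passed, and the others gave adjusted p 0.11 to 0.25. The remaining 12 lists gave adjusted p 0.0518 to 0.737. Of the tested probe sets 11097 were called, 6528 up and 4569 down, and 5997 when only the 4 samples compared were fitted. Another probe set was called the same way in 6 of 10 genes named that had others tested. All 4 of these samples were scanned on 1 day on each design, so that the comparison lies within a scan day.

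By E16.5 the tubule genes were closer to adult levels but still low. Proximal tubule genes fell in 23 of 24 and rose in 0 (0 and 23 adjusted over the list alone), with Miox (-6.68 ± 0.41, adjusted p = 8.44e-08), Slc13a3 (-5.96 ± 0.31) and the gluconeogenic gene Pck1 (-5.86 ± 0.31) first. Loop and distal tubule genes fell in 12 of 13 and rose in 0 (0 and 12 adjusted over the list alone), with Egf (-7.00 ± 0.28, adjusted p = 3.73e-09), Pvalb (-5.37 ± 0.33) and Slc12a3 (-5.27 ± 0.35) first. Proliferation genes rose in 19 of 20 and fell in 0 (19 and 0 adjusted over the list alone), Bub1 (at least 5.37 ± 0.35) and Cdk1 (5.34 ± 0.35) first. Gdnf (at least 4.68 ± 0.25) and Eya1 (4.48 ± 0.43) led 9 rises and 0 falls among 13 nephron progenitor genes (9 and 0 adjusted over the list alone). Myb (at least 2.84 ± 0.43) and Cxcr4 (2.81 ± 0.51) led 9 rises and 0 falls among 13 ureteric tip genes (10 and 0 adjusted over the list alone). Stroma genes rose in 17 of 20 and fell in 0 (18 and 0 adjusted over the list alone), with Meis1 (at least 5.11 ± 0.33), Col1a1 (4.23 ± 0.44) and Foxd1 (4.22 ± 0.33) first. Other Hox genes rose in 12 of 22 and fell in 0 (13 and 0 adjusted over the list alone), Hoxc4 (at least 2.90 ± 0.36) and Hoxc8 (2.40 ± 0.33) first.

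Macrophage genes at E16.5 fell in 12 of 16 and rose in 0 (0 and 14 adjusted over the list alone), Cd52 (-4.55 ± 0.55) and C1qa (-4.13 ± 0.49) first. Fatty acid oxidation genes fell in 8 of 11 and rose in 0 (0 and 9 adjusted over the list alone), Ehhadh (-4.83 ± 0.36) and Cpt1a (-2.42 ± 0.27) first. The ureteric trunk list split with 5 up, Gata3 (2.78 ± 0.53) first, and 4 down (5 and 4 adjusted over the list alone), Aqp2 (-3.03 ± 0.36) first. The largest rises were in Hbb-y (at least 7.49 ± 0.32), Hoxd3os1 (6.49 ± 0.70), Fignl1 (at least 6.40 ± 0.52), Fbxo5 (6.33 ± 0.37) and Igf2bp3 (at least 6.19 ± 0.23). Falls were largest in Serpina1f (-8.63 ± 0.62), Ugt3a2 (-8.39 ± 0.28 or lower), Hpd (-8.14 ± 0.36) and Rdh16f2 (-7.87 ± 0.42). The camera test passed proximal tubule (median -3.88 less all genes, whose median was 0.15; adjusted p = 1.31e-13), proliferation (3.74; 3.3e-12), loop and distal tubule (-3.60; 7.08e-07), stroma (2.14; 4.56e-06). It also passed macrophages (-2.12; 7.47e-05), fatty acid oxidation (-1.56; 0.000298), nephron progenitors (2.08; 0.00349), ureteric tip (1.66; 0.00349) and other Hox genes (0.81; 0.0187). With an estimated correlation proliferation (adjusted p = 0.00227) and loop and distal tubule (0.035) passed, and the others gave adjusted p 0.0629 to 0.255. Of the tested probe sets 13036 were called, 7526 up and 5510 down, all within 1 scan day on each design. Another probe set was called the same way in 9 of 10 genes named that had others tested, the exception being Hoxd3os1 (-0.75).

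Between consecutive wild type stages, E13.5 against E12.5 asks what changes in the first day after these early samples. Few probe sets passed: 120, with 94 up and 26 down, against 3417 at an unadjusted p under 0.05. The largest rises were in 4933438K21Rik (at least 5.18 ± 0.44, adjusted p = 0.000416), the potassium channel gene Kcnma1 (at least 3.51 ± 0.69), 1700054O19Rik (at least 3.41 ± 0.67) and Supt20 (3.37 ± 0.52). Falls were largest in the MHC class II gene H2-Aa (-3.06 ± 0.55, adjusted p = 0.0362), Rnf157 (-2.92 ± 0.37 or lower) and Sypl2 (-2.76 ± 0.52). Of the genes named so far that had other tested probe sets, 0 of 4 had one called the same way. No gene of any list passed on its own over all probe sets. As lists, camera passed early nephron up (median 0.43 less all genes, adjusted p = 6.6e-05), with values of 1.39 ± 0.35 for Cdh6 and 1.06 ± 0.39 for the Notch ligand gene Jag1 and 3 rises adjusted over the list alone. Ureteric trunk was up (0.41, 0.00873; Avpr2 1.44 ± 0.41, Upk1a 0.79 ± 0.38) and nephron progenitors down (-0.38, 0.00873; Meox1 -1.27 ± 0.31, Eya1 -0.75 ± 0.43). Proximal tubule was up (0.31, 0.0445; Hnf4a 1.35 ± 0.55, Miox at least 1.10 ± 0.41), but not with quantile normalization (median 0.02, adjusted p = 0.299; 0.0213 to 0.63 over the settings chosen beforehand). These lists had, with an estimated correlation, adjusted p 0.444 to 0.63. The count hung on single samples: it was 9 or 3 without E12.5 replicate 1 or 2, 455 or 21 without E13.5 replicate 1 or 2, and 0 when limma fitted only the 4 samples compared. Calls of 1700054O19Rik (3.32), H2-Aa (-3.04) and Sypl2 (-2.76) were lost with the actin covariate.

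From E13.5 to E16.5 the tubule segments came up. Proximal tubule genes rose in 17 of 24 and fell in 0 (18 and 1 adjusted over the list alone), with Slc27a2 (5.07 ± 0.41, adjusted p = 9.71e-06), the gluconeogenic gene Fbp1 (4.31 ± 0.41) and Slc3a1 (3.94 ± 0.37) first. Loop and distal tubule genes rose in 8 of 13 and fell in 0 (8 and 0 adjusted over the list alone), with the loop diuretic target Slc12a1 (5.11 ± 0.41, adjusted p = 1e-05), the potassium channel gene Kcnj1 (at least 4.20 ± 0.36) and Umod (3.92 ± 0.30) first. Podocyte genes rose in 9 of 15 and fell in 0 (10 and 0 adjusted over the list alone), Clic5 (3.28 ± 0.45) and Ptpro (3.11 ± 0.29) first. Ureteric trunk genes rose in 9 of 19 and fell in 0 (10 and 0 adjusted over the list alone), Aqp3 (3.73 ± 0.32) and Elf5 (2.79 ± 0.38) first. Early nephron genes rose in 6 of 16 and fell in 0 (6 and 0 adjusted over the list alone), Lhx1 (2.04 ± 0.61) and Papss2 (1.94 ± 0.33) first. Immediate early and stress genes rose in 5 of 10 and fell in 0 (6 and 0 adjusted over the list alone), the heat shock genes Hspa1b (2.29 ± 0.31) and Hspa1a (2.08 ± 0.33) and the zinc finger gene Egr1 (1.52 ± 0.34) first. The E13.5 and E16.5 samples also differed in array quality, with 430A 18S signals of 3946.3 and 3328.0 against 30398.6 and 25309.6 and Gapdh ratios of 1.986 and 2.684 against 3.305 and 4.253.

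Proliferation genes fell between E13.5 and E16.5 in 6 of 20 and rose in 0 (0 and 8 adjusted over the list alone), Birc5 (-1.77 ± 0.38) and Cdc20 (-1.25 ± 0.27) first. Markers of other cell types moved too: neuron genes fell in 3 of 8 and rose in 0 (1 and 3 adjusted over the list alone), the neurofilament gene Nefm (-2.0 ± 0.37) and Gap43 (-1.79 ± 0.34) first. In addition 1 gene each fell in the adrenal and gonad list, Nr5a1 (-2.74 ± 0.40 or lower), and in the muscle and cartilage list, Acta1 (-2.43 ± 0.55 or lower). Of 16 endothelial genes 4 rose, Sox17 (3.23 ± 0.36) and Flt1 (2.04 ± 0.41) first. Of 11 fatty acid oxidation genes 4 rose, Ppara (2.77 ± 0.72; 2.20 and not called with the actin covariate) and Ehhadh (2.50 ± 0.36) first. Sex-linked Xist (4.84 ± 1.08) and Eif2s3y (at least 3.25 ± 0.81) both rose. The largest rises of all genes were in Kdm6b (5.95 ± 0.78), the peroxisomal oxidase gene Hao2 (5.90 ± 0.31, adjusted p = 5.79e-07), Hoxd3os1 (5.87 ± 0.70) and Rtn4 (at least 5.70 ± 0.79). The largest falls were in 4933438K21Rik (-5.18 ± 0.44 or lower), Mfap4 (-4.84 ± 0.38 or lower), the embryonic globin genes Hba-x (-4.70 ± 0.40, adjusted p = 1.22e-05) and Hbb-bh1 (-4.61 ± 0.62), and Golt1b (-4.52 ± 0.45 or lower). The other probe sets of Kdm6b gave -0.78 to 1.52, those of Rtn4 0.09 to 1.70, that of Hoxd3os1 0.07 and that of Golt1b -0.08, none called.

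The camera test of E16.5 against E13.5 passed 10 lists. Up were proximal tubule (median 2.01 less all genes; adjusted p = 2.26e-13), loop and distal tubule (1.74; 1.43e-05), podocytes (1.03; 0.000249), ureteric trunk (0.92; 0.000801), immediate early genes (0.90; 0.00607) and early nephron (0.66; 0.00745). Down were proliferation (-0.47; 0.00607, and 0.0616 with quantile normalization), adrenal and gonad (-0.76; 0.0173), neurons (-0.63; 0.0424) and muscle and cartilage (-0.86; 0.0484). The adjusted p of these lists with an estimated correlation was 0.0826 to 0.245. Of the tested probe sets 6275 were called, 3502 up and 2773 down, within 1 scan day on each design. Another probe set was called the same way in 8 of 17 genes named that had others tested. The count was 2821 when only the 4 samples compared were fitted, 3731 or 4141 without E13.5 replicate 1 or 2, and 2060 or 3330 without E16.5 replicate 1 or 2.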

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

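The tests of cell share and of embryo sex were chosen after the results were seen, the comparison of probe sets of the same gene was prompted by probe sets of Zfp266 seen to differ, and the call counts with the actin covariate were known when its tests were written.

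Many probe sets differed between null and wild type kidneys, 14320 in the stage average. Of 100 splits drawn from the 108 that regroup the 12 embryonic samples within stages, 1 gave as many, the real one. The highest other gave 6457, with E12.5 and E13.5 swapped against E16.5, and the median was 0. A split that mixes the genotypes in a group raises the spread, so its low count was partly fixed. Chance is thus made unlikely but is not excluded. With the actin ratio as a covariate the folds of the called probe sets had a slope of 0.896 on those without it, and 97.1% kept their sign. Calls fell to 3395 as the median SE rose from 0.213 to 0.419. The ratio separates the genotypes completely. As the fit has a mean per group, the slope of the covariate comes only from differences between the 2 arrays of a group. The adult pair, with 430A ratios of 2.698 and 5.93, is among these groups. Folds kept with the covariate therefore cannot exclude amplification as a cause. Null E13.5 and null E12.5 shared no scan day on 430A and differed in 16 probe sets, against 3458 between null and wild type E12.5, which argues against scan day at these stages. Unequal amplification along transcripts may contribute and stays open. Called probe sets of the same gene went both ways in 22.3% of genes with several in the stage average. That is 1.83 times the highest wild type share of 12.2% (bounds set before the count were 1.2 and 2). By stage the share was 9.0%, 9.5% and 22.4% at E12.5, E13.5 and E16.5. Each lay above the 3.7%, 3.9% and 8.8% of the same wild type stage against adult, and E16.5 alone above 12.2%. Genotype, strain, pooling of kidneys and, at E16.5, the scanner and the Gapdh and 18S values also cannot be told apart.

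Endothelium and stroma genes were higher in null kidneys, by a mean of 1.214 and 0.853 less all genes in the stage average. With the actin covariate the means were 1.069 and 0.685, while that of macrophages went from 0.538 to 0.171. As the slope of the covariate comes only from differences within groups, this cannot exclude amplification as a cause. If a lower share of nephron and ureteric cells raised all other cell types alike, their lists should shift as endothelium did. Macrophage (0.538), neuron (0.153) and erythroid genes (-0.813) lay 2.457, 3.219 and 6.654 standard errors below it. These standard errors are taken over the genes of a list, which are not independent replicates, and do not measure variation between samples. The erythroid fall also grew with stage (Hbb-y -0.37, -1.17 and -3.07). An equal rise of all other cell types is not what the list means show. The nephron and ureteric lists did not move together either. Early nephron (0.589), podocyte (0.607), proximal tubule (0.18), nephron progenitor (0.032) and ureteric tip (0.038) means lay above all genes. Those of ureteric trunk (-0.136) and loop and distal tubule (-0.137) lay below. A lower share of nephron and ureteric cells stays open. Genotype, strain, tissue left beside the kidney and unequal amplification along transcripts were not tested as causes for the endothelium and stroma lists and stay open.

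Sex-linked genes differed between samples: Xist was lower in null E16.5 (-5.94, adjusted p of the stage difference 0.002) and higher at E12.5 (3.84). If each null sample is 1 embryo of 1 sex, Eif2s3y should be at the floor where Xist is above its wild type embryonic mean (log2 10.61) and above the floor elsewhere, which held in 6 of 6 null and 2 of 6 wild type embryonic samples. Xist signals were 11017.5, 13294.5 and 12832.1 with Eif2s3y at most 3.7 in both null E12.5 samples and 1 of E13.5, and at most 564.9 with Eif2s3y at least 342.2 in the other 3. Sex of the embryos may underlie the Xist differences among null samples, which share a genotype. Both genes were high in the pooled wild type E16.5 samples (Xist 14121.2 and 9191.4, Eif2s3y 462.4 and 1451.4), which a pool of both sexes would give. Neither was high at wild type E13.5 (301.5 and 525.1, 20.9 and 9.6), which weakens the reading by sex. The wild type E12.5 samples, also labelled as pooled, each read as 1 sex. Xist was 2188.2 with Eif2s3y 3.2 in the first, and 324.7 with 638.3 in the second.

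The null effect differed between stages in 4364 probe sets by the F test (14.3% of those tested), and in 52 of 115 genes named in null comparisons. These genes were named for large effects, some at a single stage, or for a small p in the same F test. Their share was therefore raised by the selection. In 26 the sign at E16.5 was opposite to that at both earlier stages, but only 13 of these were called at E16.5. In 12 sets of 6 embryonic arrays an outlier test found no single array far from the others. The sets were split by genotype and design, for median signal, actin ratio and Gapdh ratio. Such a test can miss 2 arrays that stand apart together. On 430B the null E16.5 median signals were 381.7 and 426.0, against 585.4 to 673.5 in the other null arrays. On 430A the wild type E16.5 Gapdh ratios were 3.305 and 4.253, against 1.453 to 2.684 in the other wild type embryonic arrays. Among genes largest early, with effects at E12.5, E13.5 and E16.5, Tet1 went from 5.59 to 2.03 and 0.66 (adjusted p = 0.000517), Dpysl3 from 5.24 to 2.68 and 1.92 (0.00315), Vwf from 5.20 to 1.32 and 2.51 (0.00288), Zfp704 from 5.51 to 4.16 and 2.25 (0.033) and Cpa1 from -3.47 to -1.05 and 0.18 (0.00164). Kdm6b (0.00192) went from 5.23 and 6.10 to -0.92, Dyrk2 (0.000104) from 5.13 and 5.57 to -1.25, Nfib (0.000544) from 4.52 and 5.40 to 0.69 and Zfp266 (1.25e-05) from 4.66 and 5.38 to -3.61. The wild type mean log2 over the stages was 8.52, 7.92 and 13.88 for Kdm6b and 7.83, 8.01 and 14 for Dyrk2. Their null means were 13.75, 14.03 and 12.96, and 12.96, 13.58 and 12.75. These 2 changes thus rest mostly on the wild type E16.5 samples. For Nfib (7.4, 7.04 and 10.03) and Zfp266 (7.64, 7.21 and 12.76) the wild type means rose too, while the null means fell to 10.72 and 9.14 at E16.5. Col9a1 (0.0121) went from 2.03 and 0.75 to -0.65 and Elavl4 (0.00126) from 2.05 and 1.17 to -1.24. Aldh1a1 (0.00172) and Cited1 (0.0178) fell at E12.5 and E13.5, with -0.62 and 0.09 at E16.5. The early rises of Flt1 (0.0204), Cdh5 (0.0346), Tbx18 (0.00243), Meis1 (0.00504), Greb1 (0.0298), Sox9 (0.0126), Hoxa5 (0.0111), Hoxa3 (0.0081) and Foxc2 (0.0113) gave 0.39, 0.75, -0.26, -0.34, 1.05, -0.51, 0.23, -0.13 and -0.04 at E16.5.

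Larger falls at E13.5 than at the other stages were seen in 4933438K21Rik (-5.18, adjusted p = 0.000302), D5Ertd615e (-4.40, 0.00429) and Nat8f3 (-3.84, 0.00716). Their mean log2 signals were 12.39, 11.73 and 11.05 in wild type E13.5 kidneys and at most 8.73 in every other group. These falls thus rest on the 2 wild type E13.5 samples. The F test does not say which stage differs. Effects were largest at E16.5 in Mfap4 (6.06, adjusted p = 7.89e-05), Sirt2 (4.74, 3.08e-05), Rtl3 (5.05, 0.0275), Abtb2 (4.84, 0.0428), Nphs1 (2.17, 0.0138), Hoxc5 (1.89, 0.0441), Krt19 (1.73, 0.00654), Umod (1.28, 0.0145), Mcm6 (1.27, 0.0178) and Mcm7 (0.58, 0.0422). Those that fell at E16.5 were Mapk1ip1l (-4.74, 0.000384), Rbm39 (-4.58, 0.000361), Ap1s3 (-4.53, 0.0469), Hbb-y (-3.07, 0.00464), Slc8a1 (-2.11, 0.0328), Spry2 (-2.06, 0.00191), Aqp3 (-1.90, 0.00447), Pvalb (-1.85, 0.0255), Kap (-1.81, 0.00659), Lfng (-1.46, 0.0393) and Add2 (-1.25, 0.0332). Sign changes at E16.5 were seen in Gsdme (-3.53, adjusted p = 2.62e-05), Zfhx3 (-2.39, 3e-05), Nrip1 (-0.76, 3e-05; not called at E16.5), Epha7 (-2.40, 3.78e-05) and Wdr26 (-1.47, 7.37e-05). With 1 genotype at the floor, lower bounds are the effects of Tet1, Zfp704 and Cpa1 at E12.5, of Zfp704, Cpa1, Zfp266, 4933438K21Rik and Nat8f3 at E13.5, and of Mfap4, Sirt2, Abtb2, Pvalb and Cpa1 at E16.5.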

How the results depend on the processing

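The actin covariate, the average without E16.5 and the fixed scan-day block were chosen after the data were seen; the other settings were not. Of 316 gene results named, 213 kept their call under every setting in which they were tested and 231 under those chosen beforehand; 40 were not tested with the stricter filter, 44 with only the 4 samples compared and 5 each with quantile normalization and median centring. None changed sign, but Nr5a1 in null against wild type E16.5 gave 0 with the 40th percentile floor, where both groups lie at it. The call was lost for 71 with the actin covariate, 56 with only the 4 samples compared, 30 without a filter, 17 with quantile normalization, 15 others with the 40th percentile floor, 15 with median centring and at most 8 with each other setting that kept all samples. Leaving out a replicate lost 163 calls over all genes and replicates. Hoxa11 kept its call at each stage except with only the 4 samples compared at E13.5, where its fold was -2.53 and its adjusted p 0.0504 (1e-04 to 0.0504 over the settings); that fit has fewer samples.

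With the actin covariate the counts of called probe sets fell to 779 at E12.5, 1208 at E13.5, 3395 in the stage average and 2438 in the F test; in the average the median SE rose from 0.213 to 0.419. With that covariate 1 list passed at E13.5 and 1 at E16.5. With only the 4 samples compared, and so fewer samples, 357 were called in null against wild type E13.5, 5997 in wild type E13.5 against adult and 2821 in wild type E16.5 against E13.5. Asking for at least 2-fold left 6795 in the stage average.

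The count of 120 between wild type E13.5 and E12.5 moved with most settings: 76 with quantile normalization, 76 with median centring, 62 with an offset, 260 with the 40th percentile floor, 346 with no filter, 37 with the stricter filter, 220 without the trend and 0 with only the 4 samples compared. The cause was not tested. With replicate number as a replicate block it was 72. The numbers do not pair the samples: correlations of deviations between groups passed 0.1 in 7 of 21 pairs on 430A (-0.353 to 0.281) and in 1 of 21 on 430B (-0.176 to 0.107).

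With an estimated correlation 0 lists passed in each of the 4 null comparisons and in both wild type stage steps, and 2 in each comparison with adult. With fry, which does not compare a list with other genes, 11, 9, 8 and 10 lists passed in null against wild type at E12.5, E13.5, E16.5 and averaged, 16, 19 and 15 in E12.5, E13.5 and E16.5 against adult, 0 in wild type E13.5 against E12.5 and 19 in E16.5 against E13.5.

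Leaving out a replicate leaves 1 sample in a group, assumed to vary like the other groups, and fewer samples. The counts then ranged from 2049 to 3540 at null E12.5, 3580 to 6002 at E13.5 and 6098 to 7580 at E16.5, from 3 to 455 in wild type E13.5 against E12.5, 2060 to 4141 in E16.5 against E13.5 and 1732 to 4625 in the F test. Lists past the threshold ranged from 3 to 5 at null E13.5, 1 to 5 at null E16.5, 2 to 4 in the average and 1 to 4 in wild type E13.5 against E12.5. The fold of a probe set at the floor in a group is limited by signal over background.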

Other observations

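The stage steps within null kidneys were compared after the data were seen. From E12.5 to E13.5 limma called 25 probe sets. Camera passed 3 lists up, early nephron (median 0.70 less all genes, adjusted p = 2.26e-11), ureteric trunk (0.72, 1.86e-06) and proliferation (0.34, 0.00167). It passed 3 down, macrophages (-0.69, 1.11e-06), erythroid cells (-1.04, 9.4e-05) and muscle and cartilage (-1.07, 0.00161). Of the genes of these lists 1, of early nephron, was called, and with an estimated correlation the adjusted p were 0.0774 to 0.201. From E13.5 to E16.5 it called 4594, 1783 up and 2811 down. Of 24 proximal tubule genes 17 rose and 1 fell (median 3.11 less all genes, adjusted camera p = 4.93e-18, and 0.0913 with an estimated correlation). Of 13 loop and distal tubule genes 8 rose (2.52, 3.78e-07, and 0.0583 with an estimated correlation). Of 11 fatty acid oxidation genes 7 rose (1.40, 3.17e-05, and 0.0913). Of 22 other Hox genes 1 rose and 7 fell (-0.87, 0.000142, and 0.0913), and of 8 neuron genes 5 fell (-1.33, 0.00014, and 0.0913). Camera also passed ureteric trunk (1.34, 0.000617), endothelium (0.44, 0.0203) and podocytes (0.31, 0.0282) up. Down were erythroid cells (-2.41, 0.000218), adrenal and gonad (-1.18, 0.00195), nephron progenitors (-0.74, 0.0184) and muscle and cartilage (-1.03, 0.0349). With an estimated correlation these 7 gave adjusted p 0.0913 to 0.345. The step itself differed between null and wild type in 3925 probe sets. In the other Hox list the null step less the wild type step was called above 0 for 0 genes and below 0 for 6 (adjusted camera p = 3.08e-05, and 0.226 with an estimated correlation). Null E16.5 arrays were read on another scanner and scan day than all other arrays. The later null step and the difference of steps therefore cannot be told apart from scanner and scan day. The 100 probe sets present on both designs gave log2 fold changes that correlated at 0.909 to 0.979 across probe sets, which are not independent replicates. Their medians could still differ between the designs. In null against wild type E16.5 the median was 0.189 on 430A and 0.56 on 430B, while in wild type E12.5 against adult it was 0.253 and 0.238.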
